A study of Mus musculus with 2 samples.

How the data were processed

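Splenic CD8+ T cells of wild-type mice were kept for 30 h either rested or under 1 of 5 peptide-MHC (pMHC) stimuli, stained per condition with 1 of 6 hashtag antibodies (barcoded antibodies that mark which culture a cell came from), and pooled. Per the labels' protocols, live cells were sorted with propidium iodide, fewer from the rested than from each pMHC culture, and all were loaded together into 1 lane of a 10x Genomics droplet platform. That sort removes dead cells and does not select for CD8. The libraries were sequenced on a pair of kits, which the values do not separate. Each condition was 1 culture, so there were no replicates, and no p-value, standard error or test between conditions is given.

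The deposited matrix held counts of unique molecular identifiers (UMIs) per gene and counts per hashtag for 13439 barcodes, as the authors made them with Cell Ranger 6.0.1 and bcl2fastq on GRCm38 (mm10), per the submitters' processing notes. The lowest UMI total of a barcode was 500.0. How the authors told cells from empty droplets, and the annotation they counted on, are not given in the sources used here. The matrix listed 32285 genes, of which 14268 had no UMI in any barcode. For positions, the GENCODE vM21 annotation of GRCm38 was used, which held 32235 of the gene IDs. A deposited table ties every hashtag to a condition. The hashtag features of the matrix were matched to that table by the number they share.

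Cells were given a condition from their hashtag counts alone, with Seurat 5.3.0 in R 4.3.3 (HTODemux at quantile 0.99 on centred log-ratio normalised hashtag counts). Of the 13439 barcodes, 9322 were positive for a single hashtag, 4079 (30.4%) were positive for several and were left out as multiplets, and 38 were negative. By chance, 16.9% of cell pairs join cells of 1 condition, which a hashtag cannot show, so about 831 such multiplets are expected among the cells kept. No other doublet caller was run. Cells with at least 500 genes and at most 10% mitochondrial UMIs were used, 8320 in all.

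UMIs were summed per condition and given as CPM (counts scaled to a common total per condition). A gene's ratio between conditions has an exact Clopper-Pearson 95% interval, and these intervals, like those of CPM (exact Poisson) and of shares of cells (exact binomial), cover counting error only. A gene with no count was set at a floor of 3 counts of that condition's total and its ratio is a bound. The 10 comparisons were every stimulated condition against rested cells, the higher against the lower dose of a peptide, and M9C against L6F at 20 pmol. A list member was measured at 10 CPM or more in either condition, and counted as at least 2-fold higher or lower where its ratio passed 2-fold and its interval excluded equality.

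There were 21 gene lists: Erk-linked immediate-early and feedback genes, NFAT and calcium linked genes, cytokines and chemokines, activation surface receptors, inhibitory receptors, cytotoxic effector genes, naive and quiescence genes, effector and memory transcription factors, IL-2 and STAT5 responsive genes, NF-kB responsive genes, interferon responsive genes, S phase genes, G2 and M phase genes, glycolysis genes, cholesterol synthesis genes, ribosome biogenesis genes, serine, one-carbon and nucleotide synthesis genes, integrated stress response genes, apoptosis and p53 genes, trafficking receptors, and heat shock genes. Some genes stand in several lists, such as Ifng, Il2, Irf4, Bcl2, Il2ra, S1pr1 and Ccr7. Results of some single genes are not reported here. For 3 list genes (Mx1, Aldoa and Ddit3) the symbol was not matched in the matrix. Each list has a median log2 CPM ratio, its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries, and an interval from 500 Poisson redraws of the counts. Markers of 10 cell types (CD8 T, CD4 T, gamma-delta T, B and NK cells, macrophages or monocytes, dendritic cells, neutrophils, erythroid cells and platelets) were summed per condition. No clustering was used.

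The text names genes by a rule. Per comparison it took the 10 highest and 10 lowest log2 ratios by the interval bound nearest 0, among genes at 50 CPM or more in either condition, leaving out mitochondrial, ribosomal protein, antigen receptor and unnamed genes and markers of other cell types, and it took the 2 members of every list with the largest ratio in either direction. Genes outside that rule are said to be so where they are named. Reads shared between near-identical genes make Bcl2a1b and Bcl2a1d, Ctla2a, Ly6c2 and the Gbp and Gzm families uncertain.

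To compare cells of unequal depth, each cell was thinned to 1000 UMIs, and shallower cells were left out. The activation index of a thinned cell was the log2 of its UMIs of activation receptor, cytotoxic and ribosome biogenesis genes plus 1, over its UMIs of naive genes plus 1, and the share of cells above the 99th percentile of rested cells was taken. The lists, comparisons, thresholds, naming rule and most alternatives were fixed before the data were examined.

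The calling of 2-fold members was tested on simulated counts. Drawn from 20 pmol M9C and 20 pmol L6F over 3008 genes, 100 of 100 genes at 3-fold and 0 of 100 at 1.5-fold were called, as were 0 of 2808 unchanged genes, and the interval covered the true ratio for 95.2% of the unchanged genes. Drawn from 20 pmol M9C and rested cells over 3005 genes, 100 of 100 at 3-fold, 0 of 100 at 1.5-fold and 0 of 2805 unchanged genes were called, with 95.0% covered. The simulated counts varied by counting error alone, which is what the interval assumes, so such coverage was built in. How differences between cells or cultures would change the calls was not tested. The genes drawn were the more abundant ones, so list members of low expression were not tested either.

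Alternatives were a hashtag margin rule (top hashtag at 20 or more counts and 80% or more of a cell's hashtag counts), a hashtag quantile of 0.999, no filter on cells, a stricter filter of 1500 genes and 5% mitochondrial UMIs, median-of-ratios size factors, UMIs per cell with no scaling, equal weight for every cell, no filter on low genes, 50 CPM, 1.5-fold, and leaving out cells above 3 times their condition's median UMIs or cells with no UMI of T cell markers. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.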

Results

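Antigen perception by CD8+ T cells, the cytotoxic arm of adaptive immunity, and the long-term Erk and NFAT signals that follow it are the subject of the series. Erk is a kinase and NFAT a calcium-controlled transcription factor, both downstream of the T cell receptor. Cells were read 30 h after stimulation began. The peptide named M9C (KAVYNFATM) was given at 20, 2 and 0.2 pmol, the peptide named L6F (KAVYNLATC) at 80 and 20 pmol, and rested cells were the control. The T cell receptor of the cells is not named in the sources used here.

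After filtering there were 706 rested cells, 1515 cells at 20 pmol, 1296 at 2 pmol and 1282 at 0.2 pmol M9C, and 1659 at 80 pmol and 1862 at 20 pmol L6F. Total UMIs were 918669 in rested cells and between 8786171 and 11675612 in the stimulated conditions. The median rested cell held 1060.0 UMIs and 579 genes. Stimulated cells held 5.48 to 6.47 times as many UMIs, with medians of 6667 at 20 pmol and 6862 at 0.2 pmol M9C and of 5803 at 80 pmol and 6120.0 at 20 pmol L6F. The filter on genes left out 813 of the 1521 rested singlets (53.6% with the other filter) against 1.33 to 3.75% of stimulated ones, so the rested cells described here are the deeper part of that culture. Their hashtag calls were also less clear. The hashtag margin rule gave the same call to 655 of the 706 rested cells. For M9C it did so for all 1515, 1296 and 1282 cells, and for L6F for 1658 of 1659 and 1861 of 1862. A count of 0 allows up to 3.27 CPM in rested cells and 0.257 to 0.341 CPM in the others.

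The first comparison asks what 30 h of each stimulus did to gene expression relative to rest. At 20 pmol M9C, chemokine and cytokine genes were far higher than in rested cells. Ccl4, which encodes a chemokine that draws in other leukocytes, stood at 559.3 against 13.1 CPM (42.8-fold, 95% counting interval 24.5 to 82.9), and the related chemokine Ccl3 at 450.4 against 21.8 CPM (20.7-fold, 13.4 to 33.9). Xcl1, a chemokine for cross-presenting dendritic cells, was 18.0-fold higher (7.69 to 55.6), and Il2, the T cell growth factor, stood at 31.1 against 1.09 CPM. Of 10 measured cytokines and chemokines, 6 were at least 2-fold higher and 2 at least 2-fold lower, with a list median log2 ratio of 3.82 (3.13 to 3.97), which was 0.99 with no filter on low values.

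Receptors of activated T cells went with them. Tnfrsf4, the costimulatory receptor OX40, was 42.0-fold higher (19.3 to 115), and Il2ra, the alpha chain of the IL-2 receptor, 8.76-fold (5.60 to 14.6). Among the inhibitory receptors, Cd200 was 18.7-fold (9.48 to 43.5) and Lag3 15.1-fold higher (6.92 to 41.3). At least 2-fold higher were 11 of 16 activation surface receptors (median 1.67) and 6 of 7 inhibitory receptors (median 2.84, and 1.14 with no filter on low values), with 0 and 1 at least 2-fold lower. The transcription factor genes Irf8 and Tbx21, the latter the T-bet gene of effector cells, stood at 151.5 and 32.0 CPM against 12.0 and 1.09, while the median of the 15 effector and memory transcription factors was 0.63, with 6 higher and 4 lower.

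Genes linked to the signals that the series is about were also higher at 20 pmol M9C. Of 11 measured NFAT and calcium linked genes 8 were at least 2-fold higher and 1 lower, with a median of 3.37 (2.33 to 3.68), or 2.26 with no filter on low values. Of 14 Erk-linked genes 7 were higher and 1 lower, with a median of 1.08 (0.79 to 1.79), or 0.48 at 50 CPM and -0.10 with the stricter cell filter, which kept 25 rested cells. Examples are Egr3, an immediate-early transcription factor, 9.17-fold higher (2.51 to 76.3), and Dusp6, a phosphatase that switches Erk off, at 20.3 against 1.09 CPM, but with that filter their log2 ratios were -0.13 and -0.10. Of 12 NF-kB responsive genes 9 were higher (median 1.18), led by the survival gene Bcl2a1b at 21.8-fold (9.30 to 67.2). The interferon responsive genes had a median of 0.01, with 2 higher and 2 lower of 10, although Gbp2, an interferon-induced GTPase, was 7.15-fold higher (5.48 to 9.51).

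Growth and division genes were higher at 20 pmol M9C. At least 2-fold higher were 22 of 23 S phase genes (median 1.64) and 17 of 22 G2 and M phase genes (median 1.40, and 2.55 without cells above 3 times the median UMIs, but -0.71 with the stricter cell filter). Leaving out cells above 3 times the median UMIs kept 680 of the 706 rested cells. The stricter filter kept 25 rested cells, which held 15.037% of all rested UMIs. Its value of -0.71 thus rests on few rested cells, all far deeper than the median one. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was 6.15-fold higher (4.36 to 8.95) and Ccnb1, the mitotic cyclin B1, 4.45-fold (3.09 to 6.67). In the metabolic lists, 15 of 19 cholesterol synthesis genes were higher (median 1.72), among them Idi1 at 7.07-fold (5.43 to 9.41), as were 10 of 14 glycolysis genes (median 1.44), among them Pgam1 at 4.53-fold (3.93 to 5.26). So were 12 of 18 serine, one-carbon and nucleotide synthesis genes (median 1.35), led by the mitochondrial folate enzyme Mthfd2 at 4.85-fold (3.76 to 6.37). Ribosome biogenesis genes had 9 of 19 higher (median 0.94), including nucleolin (Ncl) at 3.53-fold (3.34 to 3.74). Integrated stress response genes had 4 of 8 higher (median 1.14) and heat shock genes 3 of 7 (median 0.76, percentile 83.6 of random lists), including the mitochondrial chaperone Hspd1 at 3.83-fold (3.53 to 4.17).

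Genes of naive and recirculating T cells were lower relative to all UMIs. Rested cells also had a larger share of other common RNAs, with ribosomal protein genes at 32.5% of UMIs against 25.3 to 25.9% in stimulated cells, Malat1, a nuclear RNA, at 0.74% against 0.16 to 0.178%, Gm42418 at 2.04% against 0.451 to 0.503%, and a median mitochondrial share of 2.38% against 1.60 to 1.87%. S1pr1, the receptor that lets T cells leave lymphoid tissue, stood at 1.38 against 98.0 CPM (71.1-fold lower, 40.3 to 135), and Klf2, a quiescence factor that drives S1pr1, at 13.0 against 500.7 CPM (38.6-fold lower, 31.7 to 47.2). Of 19 naive and quiescence genes 12 were at least 2-fold lower and 0 higher (median -1.31), and of 12 trafficking receptors 10 were lower and 1 higher (median -2.19), but in UMIs per cell both medians had the other sign (1.06 and 0.17). Bcl2, a survival gene, was 11.8-fold lower (10.7 to 13.1). Ctsw, a cathepsin of cytotoxic cells, was 11.2-fold lower (9.80 to 12.8), whereas Serpinb6b was 25.4-fold higher (8.65 to 123), in a cytotoxic list with 4 higher and 2 lower of 8 (median 1.11). The IL-2 and STAT5 responsive genes (median 0.25, 2 higher and 3 lower of 12) and the apoptosis and p53 genes (median -0.33, 2 higher and 4 lower of 10) lay inside the spread of random lists, at percentiles 42.1 and 18.2.

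Against rested cells, the lower M9C doses had higher chemokine and S phase genes too, with smaller cytokine and cytotoxic medians. Ccl4 was 31.7-fold higher at 2 pmol (18.1 to 61.5) and 23.3-fold at 0.2 pmol (13.3 to 45.2), Lag3 13.9-fold and 12.8-fold, and S1pr1 stood at 1.37 and 0.91 CPM. Medians at 2 and 0.2 pmol were 3.28 and 3.18 for the NFAT and calcium linked genes, 3.27 and 2.42 for cytokines and chemokines, 0.64 and 0.33 for cytotoxic genes (the latter at percentile 47.0 of random lists), 0.77 and 0.60 for the Erk-linked genes, and 1.63 and 1.65 for S phase genes. The members measured differed between doses for some lists, so their medians do not cover the same genes. Erk-linked members were 14, 13 and 11 at 20, 2 and 0.2 pmol, NFAT and calcium linked ones 11, 11 and 10, and cytokines and chemokines 10, 10 and 9. In all lists together, 150 members were at least 2-fold higher and 38 lower at 20 pmol M9C, of 273 measured, 148 and 36 at 2 pmol, and 147 and 37 at 0.2 pmol.

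Growth lists were also higher in L6F than in rested cells, except that with the stricter cell filter the G2 and M phase medians were -0.51 at 80 pmol and -0.45 at 20 pmol. The cytokine median lay nearer to 0 than in M9C cells. At 20 pmol L6F, Gbp2 was 9.25-fold higher (7.10 to 12.3), Il2ra 8.76-fold (5.60 to 14.6), Irf8 9.94-fold, Rrm2 5.51-fold (3.91 to 8.03) and Ccl4 11.5-fold (6.54 to 22.2). The S phase and cholesterol synthesis medians were 1.69 and 1.62, with 22 of 23 and 15 of 19 members at least 2-fold higher. The medians of the cytokines and chemokines and of the Erk-linked genes were 0.94 and 0.26, over 7 and 10 measured members. Named for their M9C values, Xcl1 stood at 8.82 against 5.44 CPM, a ratio whose interval included equality (log2 0.70, -0.57 to 2.35), and Tnfrsf4 was 7.99-fold higher (3.65 to 21.8). The NFAT and calcium linked median was 2.49 at 20 pmol (9 members measured) and 1.31 at 80 pmol L6F (8 members measured). Those medians cover different members, and the direct median of 80 against 20 pmol L6F was -0.34. The interferon responsive median was 0.63 at 20 pmol and 0.75 at 80 pmol L6F. In all lists together 136 members were higher and 34 lower at 20 pmol, and 134 and 35 at 80 pmol.

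These splits against rested cells depend on the scale, as stimulated cells held more UMIs. In UMIs per cell, where the median of all genes was 2.25 to 2.47 higher on the log2 scale, 240 members were higher and 9 lower at 20 pmol M9C, 240 and 10 at 2 pmol, 238 and 7 at 0.2 pmol, 235 and 5 at 80 pmol L6F and 234 and 6 at 20 pmol L6F. With the stricter cell filter 86 members were higher and 14 lower at 20 pmol M9C. There the median of the naive genes also had the other sign (1.10), as did at 20 pmol L6F the log2 ratios of Klf2 (0.04) and Bcl2 (0.89).

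Summed in CPM, markers of several other cell types were lower in stimulated cells, but by cells with 3 or more marker UMIs, not thinned to one depth, some were not. Gamma-delta markers reached that number in 3.97% of rested cells, 2.55 to 2.77% of M9C cells and 6.07 to 6.45% of L6F cells, NK markers in 1.42% of rested and 0.528 to 2.35% of stimulated cells, and B cell markers in 0.567% of rested and 25.6 to 26.6% of stimulated cells. The genes with the lowest ratios included Mcpt8, Prss34 and Cpa3, proteases known from basophils and mast cells, at 340.7, 215.5 and 78.4 CPM in rested cells and at most 2.05, 0.26 and 0.34 CPM elsewhere. Erythroid markers summed to 526.8 CPM in rested cells and to between 1.46 and 50.8 CPM in the others, macrophage or monocyte markers to 157.8 and at most 38.9, NK markers to 175.3 and at most 63.5, gamma-delta markers to 396.2 and at most 105.5, platelet markers to 15.2 and at most 11, and neutrophil markers to 4.35 and at most 0.907. The gamma-delta sum in rested cells was mostly Trdc (363.6). The B cell sum of 650.9 CPM in rested cells was mostly Ighm (593.3), and Ms4a1 had no UMI in any condition. CD8 T cell markers summed to 5104 CPM in rested cells and 3289 to 3570 CPM in the others. The CD4 T cell sum (7.62 CPM rested, 42.0 to 277.6 stimulated) was nearly all Tnfrsf4, and the dendritic sum (3.27 rested, 37.0 to 98.1 stimulated) nearly all Batf3, genes that activated CD8 cells also use.

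**Figure D1:**
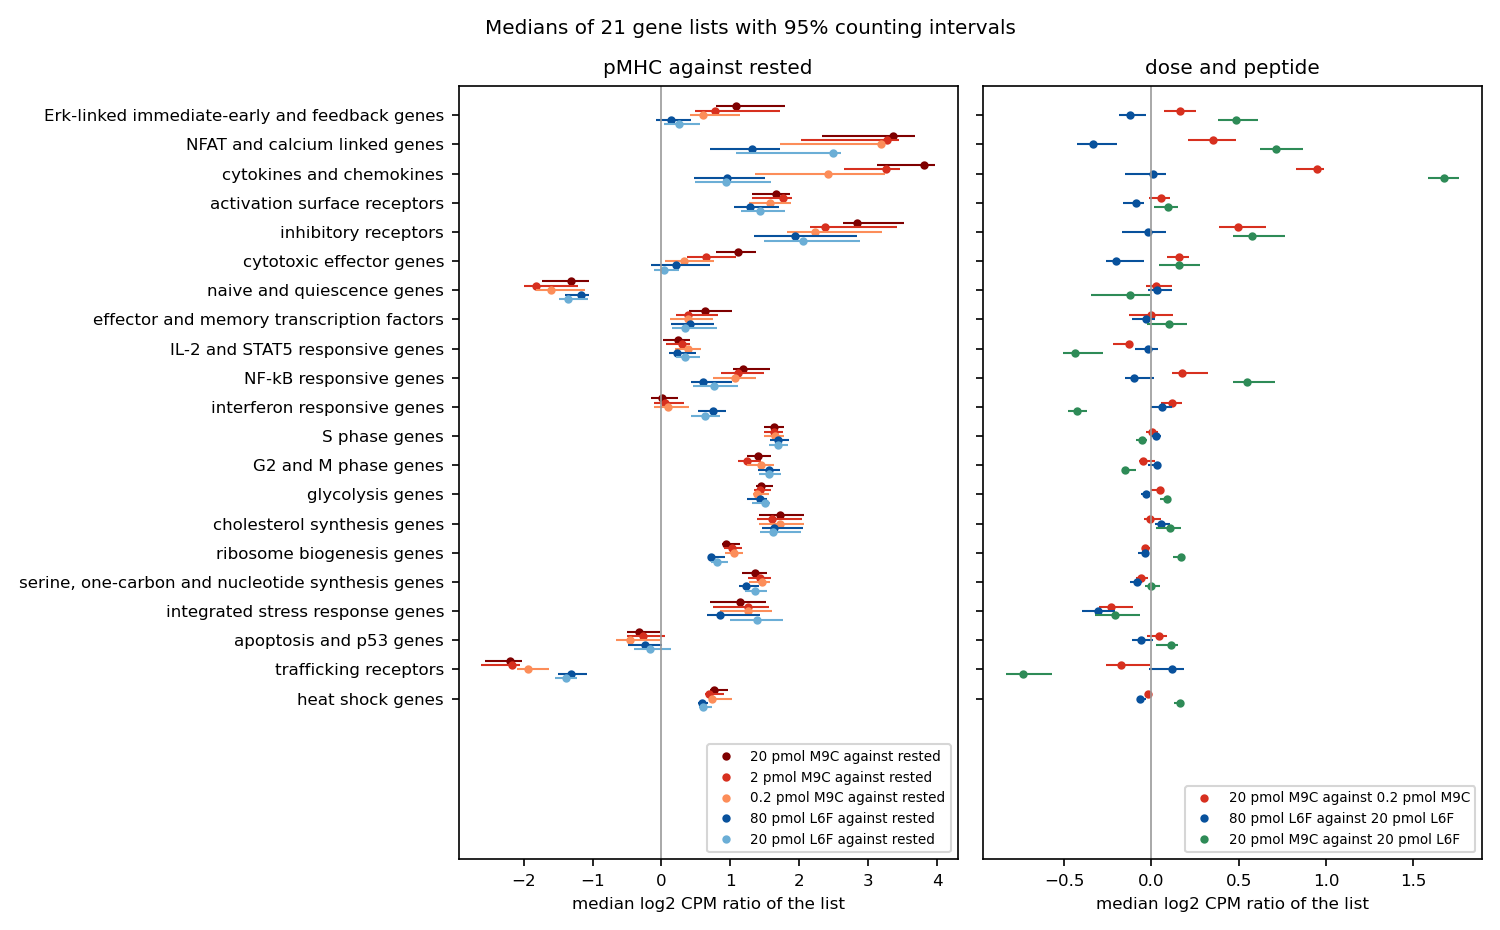
Median log2 CPM ratio (x axis) of the 21 gene lists (y axis), with the 5 stimulated conditions against rested cells on the left and, on the right, 20 against 0.2 pmol M9C (red), 80 against 20 pmol L6F (blue) and 20 pmol M9C against 20 pmol L6F (green); bars are 95% counting intervals from Poisson redraws. Cytokines and chemokines lie at 0.95 for the M9C doses, 0.01 for the L6F doses and 1.68 between peptides, over 10, 8 and 10 measured members.

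The next comparison asks how expression varied with the dose of M9C. Several cytokine and chemokine genes were higher at the higher dose. Xcl1 stood at 98.0, 64.9 and 29.0 CPM at 20, 2 and 0.2 pmol, 3.38-fold higher at 20 than at 0.2 pmol (2.94 to 3.89). Ccl1, a chemokine of activated T cells, stood at 42.4, 25.4 and 0.91 CPM (46.8-fold, 23.5 to 109), Il2 at 31.1, 21.9 and 11.3 CPM (2.74-fold, 2.18 to 3.47) and Ccl3 at 450.4, 316.6 and 221.8 CPM (2.03-fold, 1.93 to 2.14). Ifng, the interferon gamma gene, was not highest in CPM at the highest dose, with 100.2, 110.2 and 63.2 CPM. By thinned cells with an Ifng UMI the order was another, with 4.43% (3.45 to 5.60), 3.18% (2.29 to 4.28) and 3.59% (2.64 to 4.77), intervals that overlap. Those cells held on average 2.21, 3.32 and 2.22 Ifng UMIs. Lta, the lymphotoxin alpha gene, was lower at the higher dose, with 45.0, 57.2 and 70.4 CPM (log2 -0.65, -0.82 to -0.47). The list median from 0.2 to 20 pmol was 0.95 (0.83 to 0.99), and 5 of 10 members were at least 2-fold higher.

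Signal-linked genes differed less between M9C doses. The NFAT and calcium linked median was 0.35 (0.21 to 0.48) and the Erk-linked median 0.16 (0.07 to 0.25), with 2 of 10 and 2 of 14 members at least 2-fold higher. Those included Nr4a2, an orphan nuclear receptor induced by receptor signalling (2.97-fold, 2.17 to 4.13), and Spry1 and Dusp6, feedback inhibitors of the Erk pathway (2.84-fold, 2.02 to 4.05, and 2.10-fold, 1.63 to 2.74). Prf1, the gene of the pore-forming protein perforin, was 2.41-fold higher (2.01 to 2.89), and Tnfrsf4 1.76-fold (1.65 to 1.88). The inhibitory receptor median was 0.49 with 0 of 7 past 2-fold. Cell cycle, metabolic and ribosome lists lay between -0.06 and 0.05 and had 0 members past 2-fold.

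Another set was lower at the higher M9C dose. Ctla2a, which encodes a cysteine protease inhibitor, stood at 19.5, 29.6 and 88.7 CPM at 20, 2 and 0.2 pmol (4.55-fold lower at 20 than at 0.2 pmol, 3.89 to 5.35), Lgals3, the galectin-3 gene, at 18.9, 18.2 and 79.8 CPM (4.23-fold lower, 3.60 to 4.98), and Ly6c2, a surface marker of memory and effector cells, at 21, 29.1 and 70.0 CPM. Gzmb, a protease of cytotoxic granules, stood at 127.1, 136.4 and 246.4 CPM (log2 -0.96, -1.06 to -0.86). The transcription factor genes Eomes and Batf3 were lower as well, by 2.72-fold (2.25 to 3.29) and 2.66-fold (2.35 to 3.01). Their list of effector and memory factors had 4 of 15 at least 2-fold lower and a median of -0.00 (-0.13 to 0.12), at percentile 45.7 of random lists. Lyz2, a macrophage marker that goes with the same ends of the doses as Lgals3, stood at 0.69, 0.46 and 12.2 CPM. Macrophage markers reached 3 UMIs in 0, 0 and 1 cells. NK markers, which include Eomes, summed to 17.9, 24.4 and 48.6 CPM and reached 3 UMIs in 0.528, 0.617 and 2.18% of cells. Those sums were mostly Eomes itself, and the other NK markers together stood at 2.46, 3.41 and 6.69 CPM.

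Between neighbouring M9C doses, 0 of 256 measured members passed 2-fold from 2 to 20 pmol, with medians of 0.46 for cytokines and chemokines and 0.28 for NFAT and calcium linked genes. From 0.2 to 2 pmol, 3 of 257 were higher and 2 lower, and the cytokine median was 0.53. Among these members are Ccl1 (log2 4.81, 3.80 to 6.04) and, lower, Ikzf2 (log2 -1.13, -1.60 to -0.67), while Lgals3 (log2 -2.13, -2.39 to -1.88) is in no list. From 0.2 to 20 pmol, 9 were higher and 6 lower, and with 50 CPM as the limit 2 were higher and 2 lower.

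**Figure D2:**
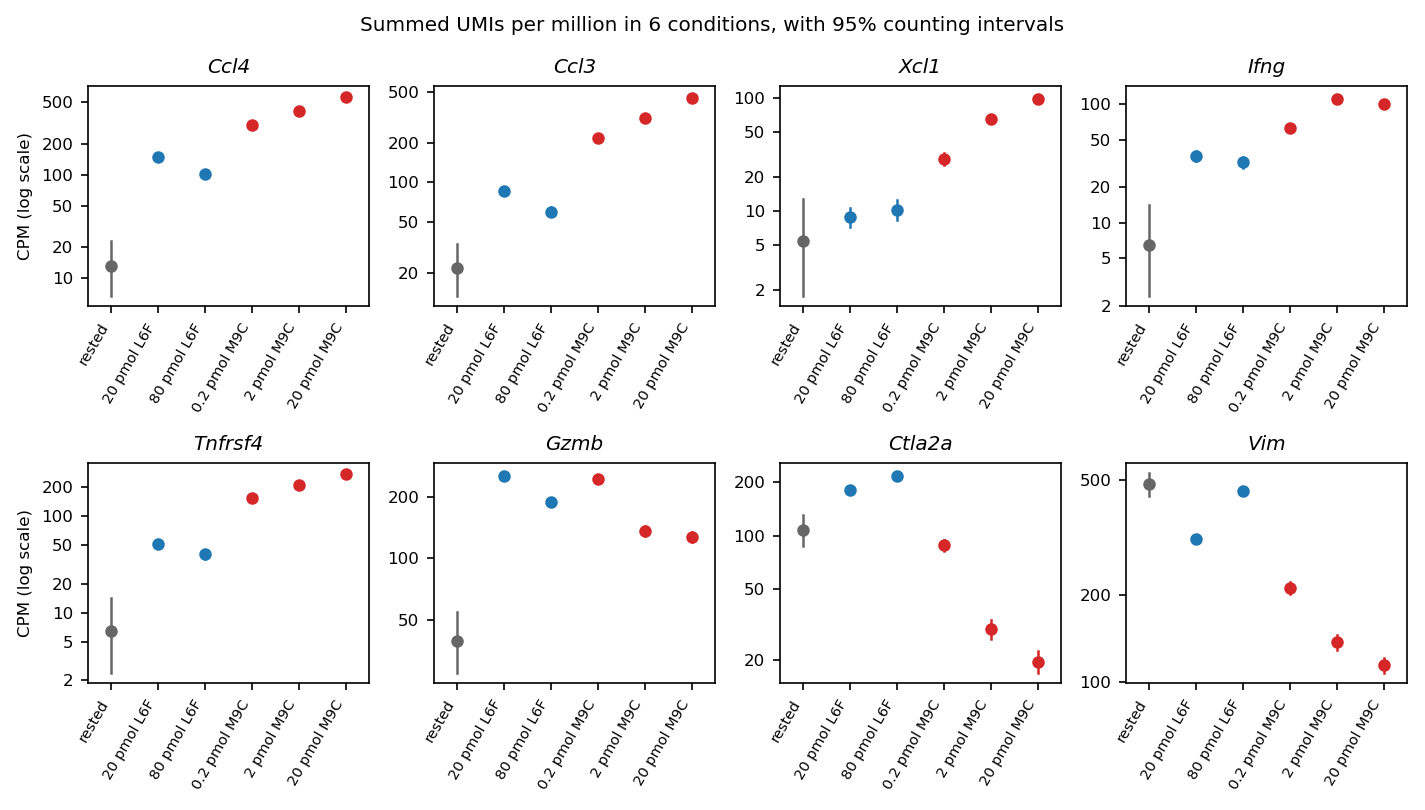
CPM (y axis, log scale) of 8 genes, chosen after their values were seen, in rested cells (grey), 20 and 80 pmol L6F (blue) and 0.2, 2 and 20 pmol M9C (red) along the x axis; bars are exact Poisson 95% counting intervals. Ccl3 stands at 21.8 CPM in rested cells, 85.7 and 59.8 at 20 and 80 pmol L6F and 221.8 to 450.4 across the M9C doses, while Ctla2a stands at 182.3 and 218.3 CPM in L6F cells and 19.5 at 20 pmol M9C.

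The L6F doses, 80 against 20 pmol, differed little. Among genes named by the rule at 50 CPM or more, the highest were Lgals3 at 79.2 against 42.6 CPM (1.86-fold, 1.66 to 2.09) and Vim, the intermediate filament gene vimentin, at 457.1 against 313.7 CPM (1.46-fold, 1.40 to 1.52). Klf2 (log2 0.59, 0.36 to 0.82) and Tcf7, a factor of naive and stem-like T cells (0.36, 0.26 to 0.45), were higher at 80 pmol, in a naive and quiescence list whose median was 0.03 (-0.02 to 0.12) with 0 of 15 past 2-fold. The chemokine genes Ccl4 and Ccl3 were lower at the higher dose, Ccl4 at 101.6 against 149.6 CPM (log2 -0.56, -0.67 to -0.45) and Ccl3 at 59.8 against 85.7 CPM (log2 -0.52, -0.67 to -0.37). Gzmb (log2 -0.43, -0.51 to -0.34) and Irf4, a transcription factor gene whose level follows receptor signal strength (log2 -0.37, -0.51 to -0.22), were lower too.

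By list, the NFAT and calcium linked median was -0.34 between L6F doses (-0.43 to -0.20, percentile 0.0 of random lists), the integrated stress response median -0.31, the cytotoxic median -0.20 and the Erk-linked median -0.12, while cytokines and chemokines were at 0.01 (-0.15 to 0.08) with 0 of 8 past 2-fold, Xcl1 among them at 10.3 against 8.82 CPM. Of 250 measured members, 1 was at least 2-fold higher and 0 lower. That member, the granzyme gene Gzmc (12.0 against 4.63 CPM), had a log2 ratio of 1.38 that was -1.71 without cells lacking T cell markers. Lyz2 stood at 33.4 CPM at 80 pmol and 0.51 CPM at 20 pmol L6F, with 4 and 1 cells holding 3 or more UMIs of macrophage markers, beside the higher Lgals3 and Vim.

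The last comparison sets the peptides side by side at 20 pmol. M9C cells had far more chemokine and cytokine RNA. Xcl1 was 11.1-fold higher than in L6F cells (9.06 to 13.7), Ccl1 11-fold (8.08 to 15.3), Il2 7.41-fold (5.47 to 10.2), Ccl3 5.26-fold (4.91 to 5.64), Ccl4 3.74-fold (3.54 to 3.95) and Ifng 2.73-fold (2.44 to 3.07). The list median was 1.68 (1.58 to 1.76), with 6 of 10 members at least 2-fold higher. Tnfrsf4 was 5.26-fold higher (4.82 to 5.76) and Cd5, a receptor that tunes T cell receptor signals, 2.07-fold (1.92 to 2.24). The inhibitory receptors Cd200 and Pdcd1, the latter encoding PD-1, were 2.94-fold and 2.91-fold higher, in a list with 2 of 7 at least 2-fold higher (median 0.58).

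Signal-linked lists were higher with M9C. The NFAT and calcium linked median was 0.71 (0.62 to 0.87), with 4 of 10 members at least 2-fold higher, the NF-kB median 0.55 with 1 of 12, and the Erk-linked median 0.48 (0.38 to 0.61) with 3 of 14. Examples are Nr4a2 (5.11-fold, 3.61 to 7.40), Spry1 (4.56-fold, 3.16 to 6.74), Ier3, an immediate-early gene (2.79-fold, 2.14 to 3.68), and the NF-kB subunit gene Rel (log2 0.97, 0.81 to 1.13). The S phase median was -0.06, the G2 and M phase median -0.15 and the ribosome biogenesis median 0.17, with 0 members past 2-fold in any of the 3 lists.

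Higher with L6F were Ctla2a at 182.3 against 19.5 CPM (log2 -3.23, -3.44 to -3.02), Ly6c2 (log2 -2.19, -2.41 to -1.98), Vim (log2 -1.46, -1.55 to -1.36) and Ms4a4b, a membrane protein gene of T cells (log2 -1.35, -1.42 to -1.28). Socs2, a feedback inhibitor induced by STAT5, had a log2 ratio of -1.59 (-1.75 to -1.43) in an IL-2 and STAT5 list with a median of -0.44 (-0.51 to -0.28). Il7r, the receptor for the survival cytokine IL-7, stood at 4.33 against 24.4 CPM, and the memory-linked factor genes Eomes and Id2 were 3.18-fold and 2.49-fold lower in M9C cells. The interferon responsive median was -0.43 (-0.48 to -0.37) with 0 of 8 past 2-fold, and examples are Gbp4 (log2 -0.76, -0.89 to -0.63) and Ifi27l2a (log2 -0.55, -0.72 to -0.38). The trafficking median was -0.74 with 0 of 8 past 2-fold. Cytotoxic genes went both ways, with 3 higher and 3 lower of 9. Prf1 was 4.25-fold higher with M9C (3.48 to 5.21), and Gzma stood at 1.57 against 16.0 CPM. Gamma-delta markers summed to 57.0 CPM in M9C and 97.6 CPM in L6F cells, mostly Trdc alone (54.8 and 91.4). NK markers, mostly Eomes, summed to 17.9 and 54.0 CPM and reached 3 UMIs in 0.528 and 1.56% of cells. In all lists together 20 of 260 members were at least 2-fold higher and 9 lower, and with 50 CPM as the limit 10 and 5.

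Single cells were compared at 1000 UMIs each, which left 430 rested cells (276 were too shallow) and 1280 to 1853 cells per stimulated condition (2 to 9 too shallow). A UMI of Ccl3 was found in 27.2% of cells at 20 pmol M9C (25 to 29.5), 19.6% at 2 pmol, 15.5% at 0.2 pmol, 5.72% at 20 pmol L6F (4.71 to 6.88) and 4.17% at 80 pmol L6F, against a background of 1.40% in rested cells (0.514 to 3.01). Without thinning these shares were 56.9, 50.1, 44.9, 20.8, 15.3 and 2.69%. For Gzmb the shares were 10.3% at 20 pmol M9C, 11.1% at 2 pmol, 16.3% at 0.2 pmol, 18.7% at 20 pmol L6F and 14.0% at 80 pmol L6F, against 1.63% in rested cells, and without thinning 35.4, 33.8, 45.5, 49.0, 38.9 and 2.41%. Mki67, a marker of cycling cells, had a UMI in 22.1 to 26.4% of stimulated and 4.88% of rested cells (68.8 to 71.7% and 7.22% without thinning). For Xcl1 the L6F shares of 1.19% at 20 pmol and 0.967% at 80 pmol lay inside the interval of the rested share (0.233%, 0.006 to 1.29). That share rests on 1 of 430 cells, so the thinned shares cannot tell the L6F values from background. Without thinning they were 3.44% (2.66 to 4.37) and 4.52% (3.57 to 5.63) against 0.708% (0.23 to 1.65), where the deeper stimulated cells have more UMIs to find.

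The activation index set the stimulated cells apart from rested ones, with more of the M9C than of the L6F cells above the limit. Its upper part includes abundant ribosome biogenesis genes. Ncl alone stood at 4995 CPM at 20 pmol M9C, against 181 CPM for Il2ra and 127 CPM for Gzmb. How much each list adds to the index was not measured. The share above the 99th percentile of rested cells was 29.2% at 20 pmol M9C (26.9 to 31.6), 29.7% at 2 pmol (27.3 to 32.3), 31.5% at 0.2 pmol (28.9 to 34.1), 23.7% at 20 pmol L6F (21.8 to 25.7) and 19.1% at 80 pmol L6F (17.2 to 21.1), against 1.16% of rested cells. The index is a range and not a cell type, as 27.8 to 36.9% of stimulated cells lay within 0.5 of the limit. Taken at the 95th percentile the share at 20 pmol M9C was 52.9%, and without thinning 8.91%.

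**Figure D3:**
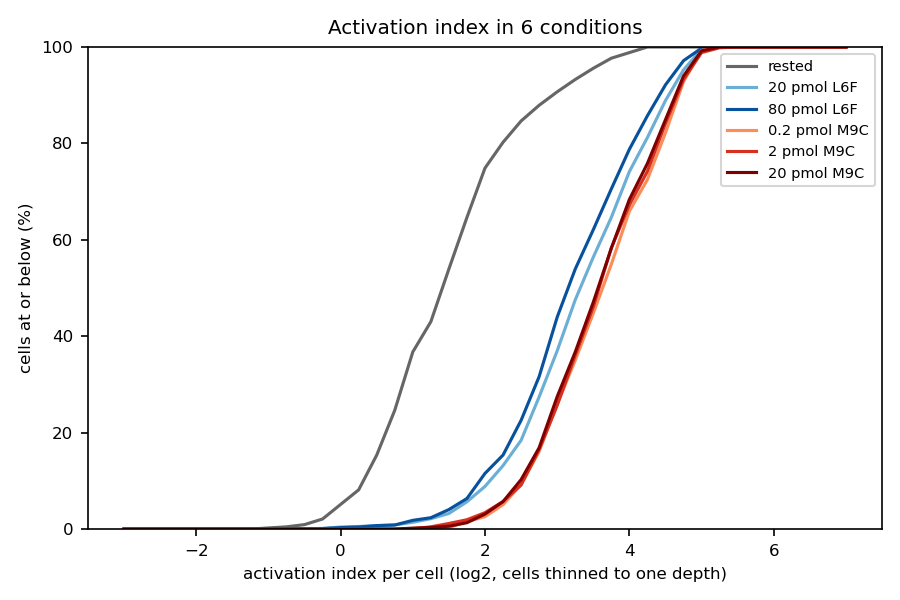
Share of cells (y axis, %) at or below each activation index (x axis, log2 units) per condition, each cell thinned to 1000 UMIs; lines are cumulative shares and carry no error bars. The median is 1.42 in rested cells, 3.17 and 3.32 at 80 and 20 pmol L6F, and 3.52 to 3.59 in the M9C conditions.

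Positions are those of GRCm38. Ccl3 (ENSMUSG00000000982) and Ccl4 (ENSMUSG00000018930) are neighbouring protein-coding genes of chromosome 11, at 83647844 to 83649355 and 83662584 to 83664683. Xcl1 (ENSMUSG00000026573) lies on chromosome 1 at 164931644 to 164935527, Il2 (ENSMUSG00000027720) on chromosome 3 at 37120523 to 37125959, Tnfrsf4 (ENSMUSG00000029075) on chromosome 4 at 156013843 to 156016612, Klf2 (ENSMUSG00000055148) on chromosome 8 at 72319033 to 72321656, S1pr1 (ENSMUSG00000045092) on chromosome 3 at 115710433 to 115715072, and Ctla2a (ENSMUSG00000044258) on chromosome 13 at 60934155 to 60936625. Counts cover whole genes, so no exon or untranslated region is told apart.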

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

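The tests of exchanged labels and of RNA content for the 6 genes named next were chosen after the result was seen, and those of RNA content for dose genes and of activated cells before.

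Among the 48 genes with the highest or lowest ratios between doses of a peptide, 6 differed between L6F doses in the direction opposite to that between M9C doses, each by 0.3 log2 or more both ways, with counting intervals that excluded equality and M9C steps of 1 sign. The log2 ratios of 80 against 20 pmol L6F were -0.52 for Ccl3, -0.56 for Ccl4, -0.45 for Cd200, -0.33 for Marcksl1 (an actin-linked signalling protein), -0.41 for Slamf1 (a costimulatory receptor) and 0.54 for Vim. Between 20 and 0.2 pmol M9C they were 1.02, 0.88, 0.60, 0.83, 0.66 and -0.89. The search was for opposite directions only, and genes that met the same limits in the same direction were not counted. Gzmb (-0.955 between 20 and 0.2 pmol M9C, -0.43 between L6F doses) and Eif4ebp1 (-0.595 and -0.36), named after their values were seen, are such genes. With 1 culture per condition the difference between the peptides was not tested. Dose genes were those at 10 CPM or more in a stimulated condition and at least 1.5-fold apart between 20 and 0.2 pmol M9C, with an interval excluding equality. The steps between neighbouring doses were not required to have 1 sign, and markers of other cells, such as Hbb-bs and Lyz2, were kept. Between L6F doses they went both ways. Of the 73 genes higher at the higher M9C dose, 40 were lower at 80 than at 20 pmol L6F (median of all 73 -0.03). For 14 of the 73 the interval lay below equality, and for 7 above. Of the 51 lower ones, 11 had an interval above and 7 below. Il2 (-1.47) and Tnfrsf4 (-0.37), named after their values were seen, were also lower at 80 pmol L6F and are not among the 6.

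A lower RNA content of the 80 pmol L6F cells stays open. In 1616 cells per condition matched on UMIs the median size of the ratio was 0.452 for the 6 genes, against 0.483 in all cells, but these genes were chosen for that size, and for the 73 genes the matched median of -0.102 decides nothing. Exchanged hashtags or labels of the L6F doses stay open, as Pearson's r across 3190 genes, which are not independent replicates, between the ratios of 80 to 20 pmol L6F and 2 to 0.2 pmol M9C was -0.1, with a Spearman's rho of 0.008, where simulated unchanged groups gave r of -0.04 to 0.046. Those groups varied by counting error alone, without differences between cultures. Fewer activated cells at 80 pmol L6F, and an effect of the dose itself, stay open too: the share above the activation limit differed by -4.586 percentage points (-7.295 to -1.877).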

How the results depend on the processing

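Chosen after the results were seen were the stricter hashtag quantile, the hashtag calls shared by both rules, totals without the commonest genes and ribosomal RNA, leaving out cells with basophil, mast or erythroid markers, and cells matched on UMIs, which gives no value against rested cells. No paired analysis was possible because every condition was a single culture in a single lane, with no replicate to pair. Of the counts of list members past 2-fold, 252 stayed within 1.5 times the value given above and 58 did not. Of list medians 2693 stayed inside the counting interval, 23 changed sign from a median of 1 or more in size, and 539 others left the interval. For named genes 4079 stayed inside, 27 ratios of at least 2-fold changed sign, and 499 others left it. These totals include settings that could not move a value. The limits of 50 CPM, no filter on low values and 1.5-fold leave every gene's ratio as it was, and 1.5-fold leaves every list median. The numbers that stayed inside are therefore no measure of robustness. The cause of a shift was not tested, except that a list limit of 50 CPM or none changes which genes are counted and a 1.5-fold limit counts smaller ratios.

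Between stimulated conditions the list medians kept their sign in all settings for cytokines and chemokines between peptides (1.21 to 1.97) and between 20 and 0.2 pmol M9C (0.63 to 1.10), for NFAT and calcium linked genes between peptides (0.69 to 0.83) and between L6F doses (-0.40 to -0.18), and for Erk-linked genes (0.39 to 0.58) and interferon responsive genes (-0.55 to -0.33) between peptides. Against rested cells, depth is a limit, as 918669 UMIs stood behind all rested values. The scale and the choice of rested cells also moved values. At 20 pmol M9C the G2 and M phase median was 2.55 without cells above 3 times the median UMIs, and the cytokine median was 0.99 with no filter on low values.

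With 1500 genes and 5% mitochondrial UMIs as the filter, 25 rested cells were left. They held 15.037% of all rested UMIs, so values against rested cells in this setting rest on few deep cells. List genes at least 2-fold higher and lower against rested cells were 86 and 14 at 20 pmol M9C, 84 and 17 at 2 pmol M9C, 87 and 13 at 0.2 pmol M9C, 73 and 14 at 80 pmol L6F, and 75 and 14 at 20 pmol L6F, and 0 were higher between L6F doses. In that order of conditions the medians of naive and quiescence genes were 1.10, 1.05, 1.15, 1.30 and 1.23 and those of G2 and M phase genes -0.71, -0.81, -0.68, -0.51 and -0.45. The Erk-linked median at 20 pmol M9C was -0.10, and the trafficking medians at 2 and 0.2 pmol M9C were 0.035 and 0.11. The log2 ratios of Egr3 were -0.13, -0.23, -0.40, -0.31 and -0.17. Those of Dusp6 were -0.10, -0.79 and -1.19 in the M9C conditions and -1.48 at 20 pmol L6F. Bcl2 had 0.14 at 2 pmol and 0.28 at 0.2 pmol M9C, 1.02 at 80 pmol and 0.89 at 20 pmol L6F, and Ctsw had 0.008, 0.37, 1.01 and 0.85 there. Ccl5, outside the naming rule, had 0.81 at 20 pmol M9C, 0.34 at 2 pmol M9C and 0.006 at 20 pmol L6F, Klf2 had 0.64 at 80 pmol and 0.035 at 20 pmol L6F, Il2 had -0.91 at 0.2 pmol M9C, and Gzmc had -0.90 between L6F doses.

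In UMIs per cell, list genes at least 2-fold higher and lower against rested cells were 240 and 9 at 20 pmol M9C, 240 and 10 at 2 pmol M9C, 238 and 7 at 0.2 pmol M9C, 235 and 5 at 80 pmol L6F, and 234 and 6 at 20 pmol L6F. In that order the naive medians were 1.06, 0.56, 0.80, 1.03 and 0.91, and the trafficking medians 0.17, 0.21, 0.47, 0.88 and 0.88. Ccl5 had 0.52 at 20 pmol and 0.044 at 2 pmol M9C.

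From 0.2 to 2 pmol M9C, 1 member was at least 2-fold lower with the margin rule, size factors, the stricter quantile, no commonest genes, no cells above 3 times the median UMIs, no cells lacking T cell markers, no basophil, mast or erythroid marker cells, and cells matched on UMIs. Between L6F doses 0 members were higher with the margin rule, without cells lacking T cell markers (Gzmc at -1.71) and at 50 CPM, and 2 were lower where every cell weighs the same and with no filter on low values, and 1 in cells matched on UMIs. With no filter on low values, 2 members were higher from 2 to 20 pmol M9C, 14 higher from 0.2 to 20 pmol, 6 higher and 6 lower from 0.2 to 2 pmol, and 16 lower in M9C than in L6F cells. At 50 CPM, 25, 23 and 22 were lower at 20 pmol M9C, 0.2 pmol M9C and 80 pmol L6F than in rested cells, 2 higher and 2 lower from 0.2 to 20 pmol M9C, 1 higher and 0 lower from 0.2 to 2 pmol, and 10 higher and 5 lower in M9C than in L6F cells. At 1.5-fold, 5 were higher and 1 lower from 2 to 20 pmol M9C, 18 higher from 0.2 to 20 pmol, 8 higher and 6 lower from 0.2 to 2 pmol, 2 higher and 2 lower between L6F doses, and 33 higher and 21 lower between peptides.

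The share of cells above the activation limit moved in each condition. At the 95th percentile of rested cells it was 52.9, 53.9 and 55.2% at 20, 2 and 0.2 pmol M9C and 37.9 and 43.6% at 80 and 20 pmol L6F. Not thinned, it was 8.91, 10.3, 11.2, 3.68 and 6.12% in that order.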

Other observations

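The test of free RNA, the overlap of dose and peptide genes and the naming of Twist1 were chosen after the results were seen. The use of UMIs per cell to judge scaling was not fixed before either. The other tests were chosen before.

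The dose genes, taken between 20 and 0.2 pmol M9C, also differed between peptides. Not all moved the same way at both dose steps: from 2 to 20 pmol Ifng had a log2 ratio of -0.14 and Hbb-bs of -2.21. Of 73 genes higher at the higher M9C dose, 67 were higher in M9C than in L6F cells (median log2 1.09), and of 51 lower at the higher dose 47 were lower, but both comparisons use the 20 pmol M9C cells. With no shared cells, the ratios of 2 to 0.2 pmol M9C and of 20 pmol M9C to 20 pmol L6F had a Pearson's r of 0.522 and a Spearman's rho of 0.207 across 3190 genes, which are not independent replicates, where 100 simulations of unchanged groups gave r of -0.045 to 0.067. The simulated groups varied by counting error alone, so the range leaves out differences between cultures. Twist1, a transcription factor gene, stood at 20.1, 7.40 and 2.95 CPM at 20, 2 and 0.2 pmol M9C and at 0.60 and 1.03 CPM at 80 and 20 pmol L6F, with no count in rested cells, which allows up to 3.27 CPM.

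Interferon responsive genes were lower at 20 pmol M9C than at 20 pmol L6F, although Ifng itself was higher. A difference in RNA content is argued against by the list median of -0.384 in 1471 cells per condition matched on UMIs. For scaling to the total, the test fixed before was size factors, which moved nothing, so their list median of -0.425 decides nothing. In UMIs per cell with no scaling, which was not fixed as a test of this, the list median was -0.33. That setting moved all genes little, to a median of 0.11 against 0.01 in CPM. A candidate explanation is a lower level of the interferon gamma receptor, as the mean log2 ratio of Ifngr1 and Ifngr2 was -0.623, with Ifngr1 at -0.65 (-0.92 to -0.38) and Ifngr2 at -0.60 (-1.29 to 0.06). Other comparisons do not decide on it. Ifngr1 stood at 239.5 CPM in rested and 28.2 CPM in 20 pmol L6F cells, where the list median was 0.63 higher. It stood at 18.0 and 19.7 CPM at 20 and 0.2 pmol M9C, where the list median was 0.12 higher at 20 pmol. Ifng itself differed there too, at 6.53 CPM in rested and 36.7 CPM in 20 pmol L6F cells, and at 100.2 and 63.2 CPM at 20 and 0.2 pmol M9C. Both the receptor level and other cells in the cultures stay open. Gamma-delta markers stood at 57.0 CPM in 20 pmol M9C and 97.6 CPM in 20 pmol L6F cells, mostly Trdc alone (54.8 and 91.4). NK markers stood at 17.9 and 54.0 CPM, mostly Eomes alone (15.45 and 49.16).

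Rested cells held 583 UMIs of Mcpt8, Prss34 and Cpa3, at 340.7, 215.5 and 78.4 CPM. Free RNA of the lane is argued against, since their sum was 265.52 times that of the highest stimulated condition (634.6 against 2.39 CPM). A few basophils or mast cells are a candidate source: 8 cells held 100.0% of these UMIs, and the 11 cells with 2 or more UMIs of 6 markers of those types held 3.69% of rested UMIs. The sort was for live cells and would not have removed them. For these genes no biological explanation was tested.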
